A study of Mus musculus with 8 samples.

How the data were processed

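The arrays were Affymetrix MG_U74Av2. Per the submitters' processing notes the signals were made with RMA (robust multi-array average), whose version is not given in the sources used here. The deposited values are on the log2 scale with 2 decimals. They were used as deposited, with no further scaling and no added constant. The table holds 12488 probe sets, of which 66 Affymetrix controls were left out of the tests, so 12422 were tested and no filter on low values was applied. Detection calls were not used here, so low values may lie near background. Of the tested probe sets 10833 carry 1 gene symbol (8251 genes), 396 carry several and 1193 none. The symbols come from the platform's own annotation, and 10817 of them matched the symbol of the same gene ID in the RefSeq gene table. That table is on GRCm38.p6 and the arrays name no build, so it served for names and for the order of neighbouring genes and no coordinates are given. No 2 arrays shared more than 2.54% of equal values.

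Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Time contrasts came from lmFit with time and genotype as terms and eBayes with a constant prior, with 2 arrays per time (1 WT and 1 EP2KO), 3 residual degrees of freedom and a prior of 7.24. The genotype contrast used the same terms, with each time pairing its WT and EP2KO array. The departure at 14 h was the interaction of genotype with the stage after ovulation in a fit with time, genotype and that interaction, with 2 residual degrees of freedom and a prior of 8.20. No paired analysis by animal was possible because replicate numbers are 1 throughout and the labels give no link between animals. P values are two-sided limma moderated tests, adjusted by Benjamini-Hochberg over the 12422 probe sets within a contrast, with a threshold of 0.05. They measure the spread among single arrays, part of which may be technical, and any difference between genotypes in the response to hCG goes into the residual of the time contrasts. The median standard error was 0.130 for a time contrast, 0.0917 for the genotype contrast and 0.209 for the departure. A gene is said to rise, fall or depart where its adjusted p is under 0.05.

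The 26 gene lists, the contrasts, the rule for named genes and the alternatives were set before the data were examined, except where the text says otherwise. The lists are cumulus matrix and expansion, EGF-like ligands and signalling, ovulatory transcription factors, prostaglandin synthesis and receptors, cAMP signalling, steroidogenesis, granulosa differentiation and FSH response, cholesterol synthesis, chemokines, chemokine receptors, integrins and cell-matrix adhesion, basement membrane and collagens, proteases and inhibitors of ovulation, innate immune and cytokine response, interferon response, glycolysis, cell cycle, heat shock and chaperones, unfolded protein response, apoptosis regulators, and markers of leukocytes, oocytes, theca and stroma, endothelium, erythroid cells and oviduct epithelium. They hold 612 symbols, of which 504 were measured, and some genes stand in more than 1 list. Each gene of a list is represented by its probe set with the highest mean. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 26 lists within a contrast, and again with an estimated correlation and with fry. With an estimated correlation no list call was kept in any contrast. A lost call need not mean a higher correlation between genes. In the time contrasts the estimate was −0.0359 for the cumulus matrix list and −0.01005 for the granulosa list, both below the preset 0.01. Yet the unadjusted camera p of the matrix list at 9 h went from 2.55e-07 to 0.01165. That of the granulosa list at 14 h went from 5.15e-07 to 0.0114. A count adjusted over the list alone uses Benjamini-Hochberg over the measured members of that list.

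Named genes were, for each tested contrast, the 12 that rose and the 12 that fell with the largest log2 change among probe sets with 1 symbol past the threshold and changed the same way in both genotypes, or at all 4 times for the genotype contrast; the departure at 14 h had no sign condition. Where fewer than 5 passed in a direction, the 5 with the smallest p that did not pass were added as values. A gene was named by the probe set with the smaller p. At single times the 6 higher and 6 lower in EP2KO with the largest difference were named among probe sets with 1 symbol and at least 1 of the 2 arrays above its median. Members of the fixed lists and Ptger2 could always be named. At single times no test was made: probe sets with an absolute log2 difference of at least 1 were counted, and the percentile of a list's median was taken among 10000 random lists of the same size drawn from 20 bins of mean expression, with a fixed seed. The correlation between the WT and EP2KO changes runs across probe sets.

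The alternatives were each array centred on its own median, quantile normalization, the lowest 40% of probe sets by mean left out, eBayes with trend and a robust prior, a threshold of 0.10, no genotype or time term, only the 4 arrays of the 2 times compared, each array or pair left out in turn, an absolute log2 difference of at least 1.5, the Spearman correlation, the average of a gene's probe sets, fry and the estimated correlation. Leaving out both 14 h arrays, leaving out the EP2KO 0 h and 3 h arrays, and taking list medians and list calls after quantile normalization were chosen after seeing the data. Where an array left out leaves a time with 1 array, that array is assumed to vary like the others.

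The tests were run on simulated arrays of the same design, with noise independent between arrays and between probe sets and 200 of 12422 probe sets changed. At a log2 change of 1, limma recovered 100% of the changed probe sets at 3 h, 9 h, 14 h and 14 h against 9 h, 98.5% for the genotype and 74.6% for the departure at 14 h. At a change of 0.5 it recovered 55.2% at 3 h, 40.3% at 9 h, 32.8% at 14 h, 49.3% for 14 h against 9 h, 91% for the genotype and 7.46% for the departure. At a change of 2 it recovered 100% in each contrast. These shares hold for arrays with 200 changed probe sets, which ease the adjusted threshold. The real genotype contrast had 0 calls, so they do not tell what share of such changes it would have found. False calls numbered 15 of 185 calls, 14 of 174, 8 of 163, 22 of 188, 9 of 202 and 5 of 126 in the same order of contrasts. In a simulated shift of 0.3 in the glycolysis list, camera found that list and 0 others. The simulated noise held no correlation between genes, while the estimated correlation of that list in the real arrays was 0.347. The simulation therefore does not check the preset correlation.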

Results

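Gene expression was measured with arrays in cumulus cells, the somatic cells that surround the oocyte and spread around it in a hyaluronan matrix before ovulation. The cells came from wild-type (WT) C57Bl/6 mice and from mice without a working Ptger2 gene (EP2KO), which encodes EP2, a receptor for prostaglandin E2. Mice of 3 to 4 weeks were given 5 IU of PMSG, which drives follicle growth, and 48 h later 5 IU of hCG, which takes the place of the ovulatory LH surge; the 0 h samples had no hCG. Counting hours from the hCG injection, 1 array per genotype was made at 0, 3, 9 and 14 h, which gives 8 arrays and no replicates. At 0, 3 and 9 h the cumulus-oocyte complexes were released from punctured ovarian follicles and the cumulus cells were stripped off by hand. At 14 h the complexes had been ovulated, were taken from the oviduct ampulla and were freed of cumulus cells with hyaluronidase, so the stage after ovulation and the way of collection go together. The labelled RNA was made from 100 ng of total RNA in 2 rounds of amplification.

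The deposited values are log2 signals. Array medians lay between 7.79 and 7.89, and the standard deviation over the probe sets of an array ran from 1.77 in WT at 0 h to 1.99 in WT at 3 h. The number of arrays limits the precision of every value. Across probe sets, which are not independent replicates, the WT and EP2KO arrays of the same time correlated with r from 0.993 to 0.995, while the highest r of an array with another time ran from 0.962 to 0.985. The difference between the 3' and 5' control probe sets of Gapdh, which grows as RNA or amplified product gets shorter, was 2.87 in WT and 2.82 in EP2KO at 14 h, against 0.80 to 1.86 in the 6 earlier arrays. For Actb it was 1.61 and 1.37 at 14 h against 0.69 to 1.54 earlier. The Gapdh difference was lowest at 3 h, at 0.80 in WT and 0.96 in EP2KO against 1.86 and 1.48 at 0 h. That of Actb was 0.73 and 0.76 at 3 h against 0.97 and 0.69 at 0 h.

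The 3 h against 0 h contrast asks which genes cumulus cells change soon after the ovulatory stimulus. The 12 genes named for the largest rises by 3 h include Ptgs2, 3 other genes of the expanding matrix and Star. Ptgs2, the inducible cyclooxygenase, rose by 6.99 ± 0.238 on the log2 scale (SE, n = 2 arrays per time; limma, adjusted p = 1.33e-07). Has2, the hyaluronan synthase, rose by 4.08 ± 0.173 (adjusted p = 5.1e-07), Ptx3, a pentraxin that organises hyaluronan, by 4.42 ± 0.183, and Tnfaip6, which couples heavy chains to hyaluronan, by 3.93 ± 0.127. Star, which moves cholesterol into mitochondria, rose by 4.11 ± 0.178. Of the other genes with the largest rises, Procr, the protein C receptor, reached 4.56, F3, tissue factor, 4.43, Ier3, an immediate early gene, 4.39 and Crem, a transcription factor of the cAMP pathway, 4.04, with 3.77 for the more highly expressed Crem probe set. Srxn1, an antioxidant enzyme, rose by 3.88, Nupr1, a stress-induced nuclear protein, by 3.78 and Mrap, an accessory protein of melanocortin receptors, by 3.77. The falls were smaller. The lowest were Wnk1, a kinase of ion transport, at −1.96, Abcd2, a peroxisomal fatty acid transporter, at −1.86, Tinf2, a telomere protein, at −1.70 and Akap8, an anchor of protein kinase A, at −1.44. Other Wnk1 probe sets stood at −1.84 and, without passing, at 0.33. Psma4, a proteasome subunit, Eid1, Ldah, a lipid droplet protein, Map3k1, a MAP kinase activator, Eif4e, the cap-binding protein, Mogat2, an acylglycerol enzyme, Fzd4, a Wnt receptor, and Asf1a, a histone chaperone, also fell, with log2 changes from −1.28 to −1.40.

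In the fixed lists, 11 of the 21 measured ovulatory transcription factors rose at 3 h, 2 fell and 8 did not pass. Cebpb rose by 2.07, Junb by 2.08, Nr4a1 by 2.06 and Pgr, the progesterone receptor, by 0.52, while Ppara fell by 0.83. Of the 16 measured genes of the cumulus matrix, 7 rose and 1 fell, among them Vcan, a hyaluronan-binding proteoglycan, with a rise of 1.45. Of 16 measured genes of cholesterol synthesis 11 rose, with Cyp51 at 1.64, Idi1 at 1.56 and Hmgcs1 at 1.40, and Insig1, a brake on the pathway, fell by 0.41. Of 18 heat shock genes and chaperones 11 rose, with Hsph1 at 0.92, Dnaja1 at 0.90 and Dnajb1 at 0.86, and 3 fell. Of 14 steroidogenesis genes 5 rose, among them Fdx1, the electron donor of the mitochondrial enzymes, at 2.5 and Hsd3b1 at 1.04, and 2 fell. Adjusted over the list alone the higher and lower counts were 11 and 2 for the transcription factors, 7 and 1 for the matrix, 11 and 1 for cholesterol synthesis, 12 and 3 for heat shock and 7 and 2 for steroidogenesis. The camera test called these lists higher than other genes, with adjusted p = 0.0021 for the transcription factors, 0.0101 for the matrix, 9.48e-04 for cholesterol synthesis, 0.0146 for heat shock and 0.0464 for steroidogenesis. With an estimated correlation the adjusted p was 0.609 for each of the 5 lists. The steroidogenesis call also ended when each array was centred on its own median (adjusted p = 0.0688), with a gene's probe sets averaged (0.232) and under quantile normalization (0.298), and the heat shock call ended under quantile normalization (adjusted p = 0.405).

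Markers of other cell types also moved by 3 h. Of 28 measured leukocyte markers 8 fell and none rose, and of 19 theca and stroma markers 7 fell and none rose, among them Insl3, a theca hormone, at −1.15 and Col1a2, a collagen, at −0.89. Over the list alone 7 leukocyte and 7 theca markers fell. Camera called both lists lower with adjusted p = 0.0336, and the adjusted p was 0.825 for leukocyte and 0.609 for theca markers with an estimated correlation; both calls ended under quantile normalization with adjusted p = 0.298, and the leukocyte call also with a gene's probe sets averaged (adjusted p = 0.0509). Fry, which asks whether the genes of a list move on balance in 1 direction and does not set them against other genes, did not pass the leukocyte list (adjusted p = 0.238). The EGF-like list, which carries the ovulatory signal through the follicle, was not called (adjusted p = 0.331), and its median of −0.13 and mean of 0.80 differed in sign. Even so, 4 of its 11 measured members rose, namely Errfi1, a feedback inhibitor of the receptor, by 2.97, Dusp6, a MAP kinase phosphatase, by 2.79, Ereg, epiregulin, by 2.69 and Btc, betacellulin, by 2.44, and 3 fell. Of 17 measured prostaglandin genes 6 rose, with Ptger4, the gene of another prostaglandin E2 receptor, at 1.97, Pla2g4a, which frees arachidonic acid, at 1.48 and Ptges, a prostaglandin E synthase, at 1.19, and 3 fell (camera adjusted p = 0.277). Of 24 genes of granulosa differentiation 10 fell, with the FSH receptor Fshr at −1.25 and Inhbb, an inhibin and activin subunit, at −1.24, and 4 rose (adjusted p = 0.176).

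In all, limma called 5313 of 12422 probe sets at 3 h, of which 2161 were higher and 3152 lower, and 570 of the former and 118 of the latter changed at least 2-fold. The 3 h arrays also had a lower 3' minus 5' Gapdh difference than the 0 h arrays in both genotypes. The median change of all probe sets was −0.135 as deposited and −0.06 with each array centred on its own median, so small falls at 3 h are to be read against that shift. Relative to the median of all genes from which lists are drawn, the leukocyte and theca lists both stood at −0.20. The share of higher calls was 2161 of 5313 as deposited, 2394 of 4505 after median centring with 4270 probe sets in common, and 1572 of 2888 with only the 4 arrays of 0 and 3 h. Without the WT 0 h array 1897 probe sets were called, without the WT 3 h array 1901, and without the EP2KO 0 h and 3 h arrays, a choice made after the data were seen, 0. In that last fit, which has few residual degrees of freedom, Ptgs2 stood at 7.44, Has2 at 4.34 and Star at 4.5, each with adjusted p = 0.0548.

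**Figure D1:**
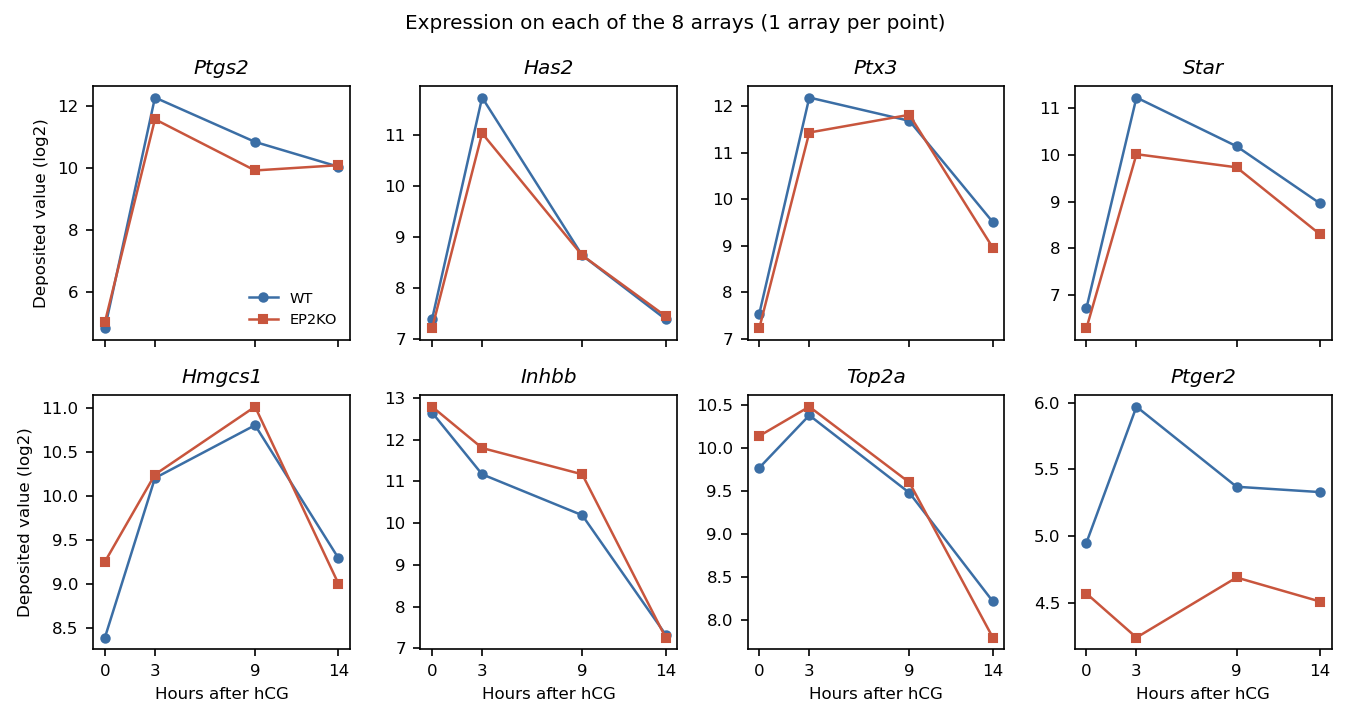
Deposited log2 value (vertical axis) against hours after hCG (horizontal axis) for 8 genes, with 1 array per point, WT in blue circles and EP2KO in red squares. Ptgs2 rose by 6.99 and Has2 by 4.08 by 3 h, Inhbb fell by 5.42 by 14 h, and Ptger2 was lower in EP2KO at each time.

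The 9 h against 0 h contrast asks what cumulus cells express late before ovulation, when expansion is under way. Ptgs2 was still up by 5.45 ± 0.238 (SE, n = 2 arrays per time; limma, adjusted p = 4.47e-07), Ptx3 by 4.36 and Tnfaip6 by 3.56. S100a6, a calcium-binding protein, rose by 5.13 ± 0.163 (adjusted p = 6.42e-08), Mgp, a matrix protein that blocks calcification, by 4.08, Alcam, a cell adhesion molecule, by 3.72, Akr1b8, an aldo-keto reductase, by 3.82 and Mt2, a metallothionein, by 3.69. At 3 h these 5 had risen by 1.76, 3.56, 2.29, 3.29 and 1.76. Nupr1 was up by 4.78, Procr by 4.28, Mrap by 4.01 and Ier3 by 3.86. Inhbb fell by 2.04 ± 0.213. Nr5a2, a nuclear receptor of granulosa cells, stood at −1.80, with −0.95 for its more highly expressed probe set, and Aldh1a1, an enzyme of retinoic acid synthesis, at −2.27. Also down were Hpgd, which breaks down prostaglandins, at −2.12, Mycn, a growth-promoting transcription factor, at −2.0 and a probe set of Ddx6, an RNA helicase, at −2.08, with −1.46 and −0.55 for the others. Abcd2, Tenm4, a membrane protein of cell contacts, Dock9, a guanine nucleotide exchange factor, Limch1, Psma4 and Xist, the RNA of X inactivation, fell as well, with log2 changes from −1.82 to −2.14.

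Of 16 measured cholesterol genes 12 rose and none fell, with Hmgcs1 at 2.08, Msmo1 at 1.86 and Idi1 at 1.41 (camera adjusted p = 7.74e-08; adjusted p = 0.473 with an estimated correlation). Of 16 matrix genes 8 rose and none fell, with Lox, which crosslinks collagen, at 3.48 and Vcan at 2.06 (adjusted p = 2.21e-06; 0.167 with an estimated correlation). Of 31 cell cycle genes 15 fell and 1, Cks2, rose by 1.08; Cdc6, which loads the replicative helicase, stood at −1.47, Kif11, a spindle motor, at −1.39 and Mcm7 at −1.14 (adjusted p = 9.39e-07; 0.521 with an estimated correlation; 0.0633 in fry). Of 24 granulosa genes 13 fell and none rose, with Fshr at −1.69, Bmpr1b at −1.64, Inhba at −1.40 and Esr2, an estrogen receptor, at −1.22 (adjusted p = 9.6e-06; 0.167 with an estimated correlation). Of 17 proteases and inhibitors 9 rose, with Timp1 at 1.97 and Timp3 at 1.12 (adjusted p = 0.0014; 0.517 with an estimated correlation). Of 21 basement membrane genes 7 rose and 1 fell, with Col4a1 at 2.64 and Sparc at 1.94 (adjusted p = 0.00471; 0.521 with an estimated correlation). Of 21 ovulatory transcription factors 9 rose and 2 fell, with Cebpb at 2.32 and Cebpd at 1.40 (adjusted p = 0.00465; 0.521 with an estimated correlation; 0.0764 in fry). Adjusted over the list alone, 13 cholesterol genes rose and 1 fell, 10 matrix genes rose, 21 cell cycle genes fell and 1 rose, 14 granulosa genes fell, 10 proteases and inhibitors rose, 8 basement membrane genes rose and 1 fell, and 9 transcription factors rose and 2 fell. Of 17 glycolysis genes, which was not a called list (adjusted p = 0.0894), 8 fell and 2 rose, with Pfkl at −1.33, Pfkp at −1.31 and Pkm at −1.03, while Hk2, a hexokinase, rose by 1.23.

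In all, limma called 2852 probe sets at 9 h, 1353 higher and 1499 lower, of which 389 and 160 changed at least 2-fold. The leukocyte, theca, oviduct and endothelial lists were not called at 9 h, and of the 6 erythroid markers the haemoglobin genes Hba-a1 and Hbb-b2 rose by 2.17 and 1.70. These rises rest mostly on the WT 9 h array, where Hba-a1 read 13.39 and Hbb-b2 10.34. In EP2KO they read 10.94 and 7.98 at 9 h. At 0 h they read 9.79 and 7.17 in WT and 10.21 and 7.76 in EP2KO. Without the WT 0 h array 1225 probe sets were called, without the WT 9 h array 1386 and without the EP2KO 9 h array 1327.

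The 14 h against 0 h contrast compares ovulated cumulus cells with those of follicles given PMSG but no hCG. The 12 genes named for the largest rises include the matrix proteins Tnc and Col4a1, and the 12 for the largest falls include Inhbb, Hsd17b1 and Ccnd2. S100a6 rose by 5.27 ± 0.163 (SE, n = 2 arrays per time; limma, adjusted p = 3.59e-08), Emp1, a membrane protein, by 4.30 ± 0.119 (adjusted p = 1.62e-08), Col4a1, a basement membrane collagen, by 4.00 ± 0.204, and Tnc, tenascin C, by 4.56, with 3.43 for its more highly expressed probe set. Abcb1b, a drug efflux transporter, rose by 5.15, Ptgs2 by 5.13, Lgals3, galectin 3, by 4.67, Sgk1, a kinase of salt transport, by 4.48 and Ier3 by 4.33. Pcsk5, a proprotein convertase, rose by 4.20, Anxa1, an annexin of resolving inflammation, by 4.17 and Acsl4, which activates arachidonic acid, by 4.15. Inhbb fell by 5.42 ± 0.213 (adjusted p = 1.39e-07), with Hsd17b1, which makes estradiol, at −3.62 and Ccnd2, cyclin D2, at −2.71. Also down were Car14, a carbonic anhydrase, at −3.29, Tnni3, a troponin, at −3.13, Rasd1, a small GTPase, at −3.03, Hpgd at −3.02, Mycl at −2.96, Aldh1a1 at −2.94, Pclaf, a PCNA-binding protein, at −2.83, Tenm4 at −2.81 and Rnaseh2b at −2.75.

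Of 31 measured cell cycle genes 28 fell at 14 h and none rose, with Cdc6 at −2.44, Mcm3 at −2.40, Birc5 at −2.23 and Mki67 at −1.99 (camera adjusted p = 4.26e-16; adjusted p = 0.351 with an estimated correlation). Of 24 granulosa genes 14 fell, with Esr2 at −2.71, Inhba at −2.14 and Fshr at −1.75, and 1 rose, Foxo3 by 0.94 (adjusted p = 4.46e-06; 0.160 with an estimated correlation). Of 21 basement membrane genes 11 rose and none fell, with Sparc at 2.71, Col4a2 at 2.53 and Lamb1 at 1.92 (adjusted p = 1.05e-05; 0.351 with an estimated correlation). Of 16 matrix genes 10 rose and none fell, with Lox at 3.71 and Fn1, fibronectin, at 1.98, while Has2 stood 0.12 above 0 h and did not pass (adjusted p = 4.46e-06; 0.160 with an estimated correlation). Of 22 integrin and adhesion genes 10 rose, with Vcl, vinculin, at 3.29 and Itgb1 at 1.66 (adjusted p = 6.17e-04; 0.269 with an estimated correlation), and of 17 proteases and inhibitors 10 rose, with Timp1 at 2.79, Plat, tissue plasminogen activator, at 2.02 and Ctsb, a cathepsin, at 1.86 (adjusted p = 2.33e-04; 0.351 with an estimated correlation). Of 21 ovulatory transcription factors 13 rose, with Egr2 at 1.79, and 2 fell, Pparg at −2.12 and Epas1 at −0.46 (adjusted p = 0.00109; 0.479 with an estimated correlation). Of 14 steroidogenesis genes 7 rose, with Cyp11a1, which starts steroid synthesis from cholesterol, at 3.11 and Fdx1 at 2.79, and 3 fell (adjusted p = 0.0477; 0.479 with an estimated correlation); this call ended after median centring (adjusted p = 0.0626), with a gene's probe sets averaged (0.109) and under quantile normalization (0.0538). Adjusted over the list alone, 28 cell cycle genes fell, 17 granulosa genes fell and 1 rose, 12 basement membrane genes rose and 1 fell, 10 matrix genes and 10 proteases and inhibitors rose, 10 integrin genes rose and 1 fell, 15 transcription factors rose and 2 fell, and 8 steroidogenesis genes rose and 3 fell.

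Of 27 measured innate immune and cytokine genes 12 rose at 14 h, with Il1r1 at 2.45, Socs3 at 1.65 and Il1rn at 1.23, and 2 fell, among them Socs2 at −1.84 (camera adjusted p = 6.17e-04; 0.479 with an estimated correlation). Alcam at 3.52 and Pdcd1, an immune checkpoint receptor, at 2.83 are in that list too. Of 23 interferon response genes 12 rose, with B2m at 1.83, Irf9 at 1.83 and H2-D1 at 1.25, and 1 fell (adjusted p = 0.00182; 0.479 with an estimated correlation). Beside them, 12 of 28 leukocyte markers rose and none fell, with Ctss, a cathepsin of myeloid cells, at 2.96, S100a8 at 2.0, Cd53 at 1.94 and Lyz2, lysozyme, at 1.69, while Ptprc, the pan-leukocyte CD45, stood at −0.18 and did not pass (adjusted p = 5.4e-04; 0.671 with an estimated correlation). Fry did not pass this list (adjusted p = 0.103). Adjusted over the list alone, 14 innate genes rose and 2 fell, 12 interferon genes rose and 2 fell, and 12 leukocyte markers rose. Of 25 chemokines, a list known to be of interest from an earlier report on these mice and so not independent evidence, 6 rose, 5 over the list alone, with Ccl2 at 1.66 and Cxcl2 at 1.43 (adjusted p = 0.174). The Ccl2 value rests mostly on the EP2KO 14 h array, which read 7.44 against 5.46 in WT, from 4.69 and 4.89 at 0 h. Of 19 oviduct epithelium markers 5 rose and 1 fell (adjusted p = 0.0644), and Ovgp1, the oviduct-specific glycoprotein, read 11.13 in WT and 11.46 in EP2KO at 14 h against 7.05 to 7.76 before. Of 14 endothelial markers 2 rose, Ramp2 by 2.46 and Cdh5 by 1.55, and 2 fell. No theca marker passed at 14 h.

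In all, limma called 3575 probe sets at 14 h, 1682 higher and 1893 lower, of which 574 and 400 changed at least 2-fold. Without the WT 0 h array 2289 were called. The 14 h arrays differ from the others in collection and in the Gapdh control ratio as well as in time.

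**Figure D2:**
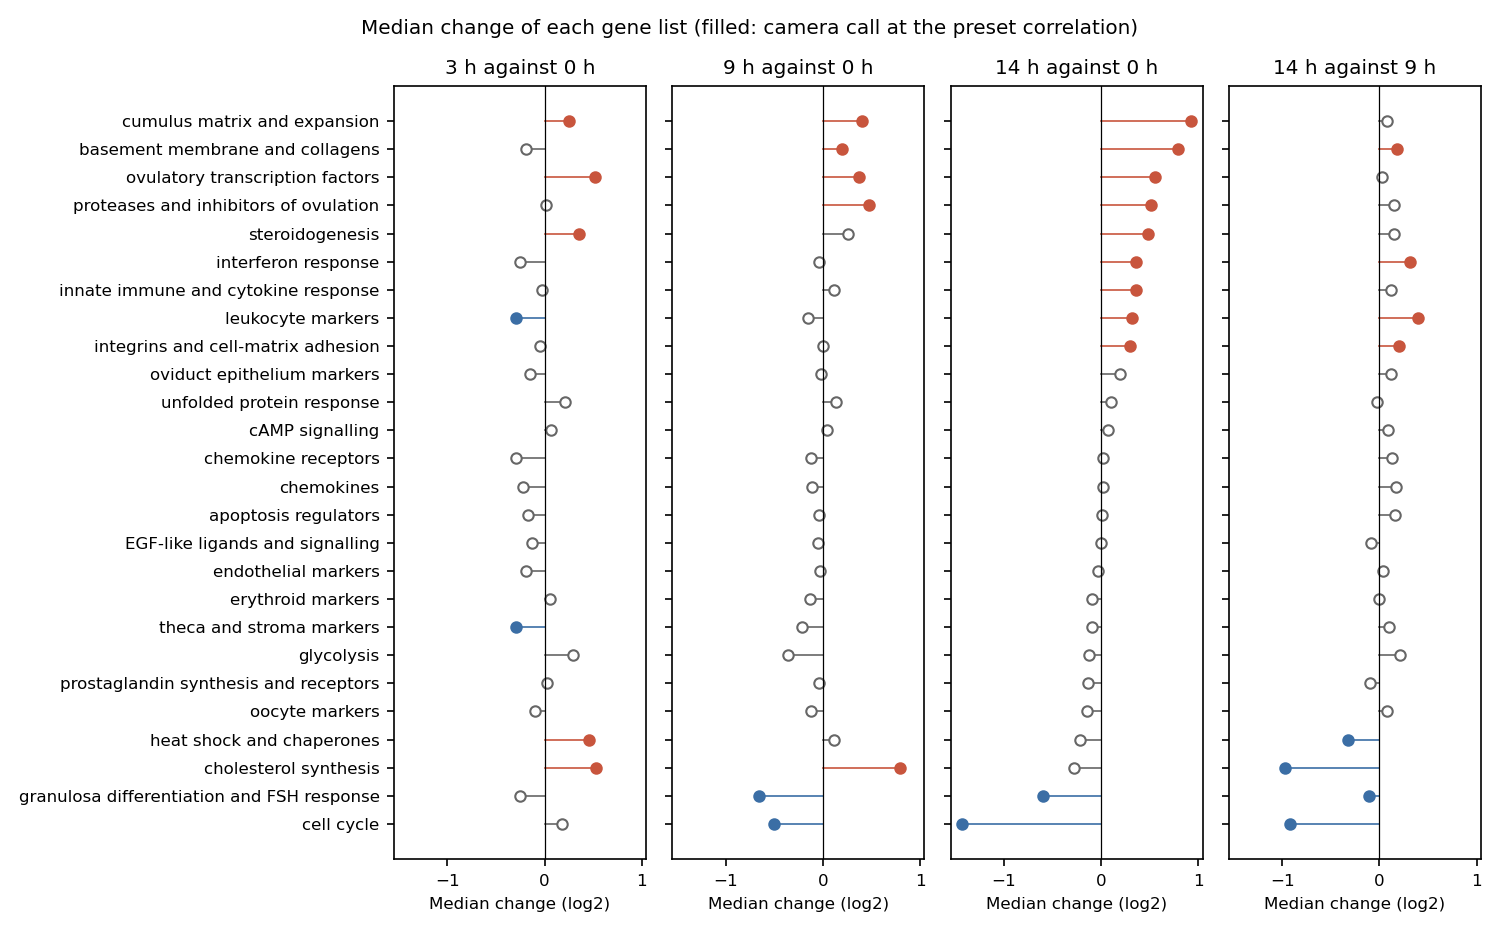
Median log2 change (horizontal axis) of each of the 26 gene lists (vertical axis) in the 4 time contrasts, filled in red or blue where camera called the list higher or lower at the preset correlation and open where it did not. At 14 h against 0 h the cell cycle list lies lowest at −1.43 and the cumulus matrix list highest at 0.93; no call was kept with an estimated correlation.

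The 14 h against 9 h contrast sets cumulus cells after ovulation against those shortly before it. Most measured genes of cholesterol synthesis and of the cell cycle fell, and 8 of 22 integrin and adhesion genes, 10 of 23 interferon genes and 12 of 28 leukocyte markers rose. Ovgp1 rose by 3.81 ± 0.151 (SE, n = 2 arrays per time; limma, adjusted p = 8.75e-07), Tnc by 3.42, with 2.92 for its more highly expressed probe set, Emp1 by 3.12 and Abcb1b by 2.44. Saa3, an acute-phase protein, rose by 2.89, Lgmn, a lysosomal protease, by 2.73, Atp13a3, a polyamine transporter, by 2.75, Gas1 by 2.63 and Itm2a by 2.58. Lilr4b, an immunoglobulin-like receptor of leukocytes, rose by 3.46, Arg1, arginase, by 3.25 and Ctss by 3.01. Inhbb fell by 3.38 ± 0.213, with Hsd17b1 at −2.67, Ptx3 at −2.51 and Msmo1, an enzyme of cholesterol synthesis, at −2.33. Mvk, mevalonate kinase, stood at −2.42 on its named probe set and at −0.67 on its more highly expressed one. Also down were Gsta4, a glutathione transferase, at −2.87, Prmt1, an arginine methyltransferase, at −2.73, Gpr83 at −2.60, Pdlim1 at −2.49, Mt1, a metallothionein, at −2.30, and Elob and Atp5e, a subunit of ATP synthase, at −2.25 each.

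Of 16 measured cholesterol genes 13 fell and none rose, with Idi1 at −1.82, Hmgcs1 at −1.76 and Sqle at −1.65 (camera adjusted p = 4.2e-10; adjusted p = 0.513 with an estimated correlation). Of 31 cell cycle genes 22 fell and none rose, with Birc5 at −1.83, Cdc20 at −1.73 and Aurka at −1.65 (adjusted p = 1.27e-13; 0.513 with an estimated correlation). Of 18 heat shock genes and chaperones 7 fell, with Hspe1 at −1.29, Hspa5 at −0.96 and Bag3 at −0.93 (adjusted p = 0.0033; 0.515 with an estimated correlation), and of 24 granulosa genes 6 fell and 2 rose (adjusted p = 0.036; 0.513 with an estimated correlation), a call that ended under quantile normalization with adjusted p = 0.0815. Of 21 basement membrane genes 9 rose, with Col4a2 at 1.57 and Col4a1 at 1.36 (adjusted p = 3.74e-04; 0.513 with an estimated correlation), and of 22 integrin and adhesion genes 8 rose, with Vcl at 2.15 and Fn1 at 1.61 (adjusted p = 0.00183; 0.513 with an estimated correlation). Of 23 interferon genes 10 rose, with Irf9 at 1.12 and Gbp2 at 0.95 (adjusted p = 5.71e-04; 0.513 with an estimated correlation). Beside these, 12 of 28 leukocyte markers rose, with S100a8 at 2.12 and Cd53 at 2.10 (adjusted p = 1.9e-06; 0.516 with an estimated correlation; 0.069 in fry), and 5 of 19 oviduct markers rose, among them Krt18 by 1.5, without a list call (adjusted p = 0.0989). Adjusted over the list alone, 13 cholesterol, 25 cell cycle and 7 heat shock genes fell, 6 granulosa genes fell and 2 rose, and 9 basement membrane, 10 integrin, 11 interferon and 13 leukocyte genes rose. The cumulus matrix list was not called (adjusted p = 0.724), with a median of 0.08 and a mean of −0.03: Fn1 and Sdc4 rose by 1.61 and 1.01, while Ptx3 and Has2 fell, to −2.51 and −1.22.

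In all, limma called 2496 probe sets between 9 and 14 h, 1247 higher and 1249 lower. With only the 4 arrays of these times 699 were called, and Lilr4b, Arg1, Ctss and Hsd17b1 no longer passed (adjusted p = 0.0621, 0.0662, 0.0568 and 0.0581) although their log2 changes were the same; without the EP2KO 9 h array 1286 were called.

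The remaining lists gave no call in any of the 4 time contrasts. Chemokine receptors had 2 members higher and 7 lower at 3 h, with Ackr3 and Cxcr4 both at 0.98, and 4 higher at 14 h. In cAMP signalling 7 of 26 rose and 5 fell at 3 h and 6 rose and 2 fell at 14 h; Rgs2 rose by 1.07 and Prkar1a by 1.11 at 3 h. In the unfolded protein response 9 of 20 rose and 3 fell at 3 h, with Atf4 at 1.65 and Pdia3 at 1.26. Among 24 apoptosis regulators 4 rose and 7 fell at 3 h, and Gadd45a, a growth arrest gene, rose by 1.03 at 3 h and 3.27 at 14 h. Of 20 oocyte markers 1 rose and 4 fell at 3 h, 3 fell at 9 h, and 3 rose and 2 fell at 14 h; those that rose at 14 h were Plat, Bmp6 and Spin1, by 2.02, 1.33 and 0.93. Of 6 erythroid markers 2 rose and 3 fell at 3 h. A list's median, mean and test direction differed in sign for 4 lists at 3 h, 7 at 9 h, 4 at 14 h and 2 for 14 h against 9 h, and camera called none of these.

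The change in WT and the change in EP2KO from 0 h, which share no array, were compared across the 12422 probe sets. Pearson's r was 0.858 at 3 h, 0.887 at 9 h and 0.850 at 14 h, and Spearman's rho 0.776, 0.786 and 0.698; genes are not independent replicates, so no test was made. At 3 h 904 probe sets rose at least 2-fold in value in WT and 338 in EP2KO, with 323 in both, while at 9 h the numbers were 477, 367 and 308 and at 14 h 729, 521 and 428. At least 2-fold lower were 299 in WT and 97 in EP2KO at 3 h, 180 and 176 at 9 h, and 352 and 542 at 14 h. A single probe set went opposite ways by that much at 3 h and none did at 9 or 14 h. The standard deviation of the changes at 3 h was 0.660 in WT and 0.455 in EP2KO. That of the arrays went from 1.77 at 0 h to 1.99 at 3 h in WT and from 1.84 to 1.96 in EP2KO. A fixed 2-fold cut also counts such spread, all WT changes share the WT 0 h array, and no such count was made after normalization.

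The EP2KO against WT comparison over all times asks which genes the loss of EP2 changes, with the 4 times as 4 pairs. The targeted gene, Ptger2, read 4.95, 5.97, 5.37 and 5.33 in WT and 4.57, 4.24, 4.69 and 4.51 in EP2KO at 0, 3, 9 and 14 h. It was lower in EP2KO at 4 of 4 times, at −0.90 ± 0.176 (SE, n = 4 pairs; limma, adjusted p = 0.528), and its mean lay at percentile 7.58 of all probe sets. Whether its probe set lies in the deleted part of the gene is not given in the sources used here, and a probe set outside it checks nothing. No probe set passed in limma, with a smallest adjusted p of 0.308, and 642 had an unadjusted p under 0.05 where 621 are due by chance. The genes with the smallest p, which did not pass, each differed the same way at 4 of 4 times. Lower in EP2KO were Star at −0.69, Tnfaip6 at −0.46, Efnb2, an ephrin ligand, at −0.76 and a Ddx6 probe set at −0.59 (adjusted p between 0.308 and 0.528), with −0.20 and −0.13 for the other Ddx6 probe sets. Higher were Ccn2, a matrix growth factor, by 0.78, Cadps by 0.62, Polr2e by 0.48, Slfn4 by 0.43 and Mvd, an enzyme of cholesterol synthesis, by 0.43 (adjusted p between 0.528 and 0.582). Without the 14 h pair a single probe set passed, one with no gene symbol, looked up after the result was seen.

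Among the lists, the cumulus matrix genes were the ones most uniformly lower in EP2KO, 15 of 16 measured, with a median of −0.16. Sdc1 stood at −0.38, Ptx3 at −0.37, Ptgs2 at −0.34 and Vcan at −0.32. No member passed over all genes and 3 were lower adjusted over the list alone (camera adjusted p = 3.08e-08; adjusted p = 0.190 with an estimated correlation). This call was kept without each pair in turn, and fry, the test of movement in 1 direction, passed it alone among the 26 lists (adjusted p = 0.0323). Camera also called the EGF-like list lower (median −0.04, adjusted p = 0.0223; 0.572 with an estimated correlation), with Ereg at −0.58, and the ovulatory transcription factors (median −0.09, adjusted p = 0.00509; 0.705 with an estimated correlation), with Nr4a1 at −0.55 and Runx1 at −0.51. It called cAMP signalling lower (median −0.06, adjusted p = 0.023; 0.572 with an estimated correlation) and the basement membrane list (median −0.07, adjusted p = 0.0114; 0.705 with an estimated correlation). Higher in EP2KO were glycolysis, 15 of 17 genes (median 0.15, adjusted p = 0.0223; 0.765 with an estimated correlation), and the cell cycle, 23 of 31 (median 0.08, adjusted p = 0.0114; 0.772 with an estimated correlation). The list alone gave 0 genes in each of these 6 lists. Without the 3 h pair 4 lists were called and without the 14 h pair 12, and each of these 6 calls ended without at least 1 pair. At 0, 3, 9 and 14 h glycolysis had medians of 0.31, 0.01, 0.37 and −0.08, and the cell cycle 0.19, 0.19, 0.25 and −0.20. The 3' minus 5' Gapdh control differed between genotypes by −0.38, 0.16, −0.49 and −0.05 at the same times. The median, mean and test direction differed in sign for 4 uncalled lists, namely steroidogenesis, innate immune, interferon and oocyte markers.

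The series sets cells before ovulation against cells after it, so the EP2KO minus WT difference at 14 h was tested for departure from that at 0, 3 and 9 h. Some chemokines and genes of myeloid cells stood higher in EP2KO at 14 h. For Ccl2, a monocyte attractant, the difference departed by 1.95 ± 0.217 (SE, 1 pair at 14 h against 3 before, limma adjusted p = 0.0357), from −0.20, 0.10 and 0.18 to 1.98. Cxcl1, a neutrophil attractant, departed by 1.63 ± 0.212 and stood at 1.76 at 14 h, with 1.17 for its more highly expressed probe set. Arg1 departed by 1.80, Krt18, a keratin, by 1.76, Lilr4b by 1.61 and Ctss by 1.5 (adjusted p between 0.0357 and 0.0466); another Krt18 probe set stood at 0.01 at 14 h. Bnip3, a mitophagy receptor, departed by −1.56 and Hmgb2, a chromatin protein, by −1.57 (adjusted p = 0.0466 for each). Ak4, an adenylate kinase, at −1.33, Eid1 at −1.23, Fubp1 at −1.33, Zfp322a at −1.14 and Ptch1 at −1.08 did not pass (adjusted p from 0.0537 to 0.140). In all 10 probe sets passed, 8 up and 2 down, and 865 had an unadjusted p under 0.05 where 621 are due. Ccl2 kept a value between 1.84 and 2.03 in each alternative that includes it. None passed after median centring, with the lowest 40% of probe sets left out, or without the 0 h, the 3 h or the 9 h pair, and the test takes the single 14 h pair to vary like the 3 before it. In the earlier arrays Ccl2 read 4.69 to 4.99 and Lilr4b 4.35 to 4.60, which may lie near background. Their spread there may understate that at the higher 14 h values.

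Of 28 leukocyte markers 26 had a positive departure, with a median of 0.41, 1 passing over all genes and 9 over the list alone, and S100a8 stood at 1.22 and Lyz2 at 1.18 (camera adjusted p = 1.22e-12; adjusted p = 0.411 with an estimated correlation). Of 25 chemokines, the list of known interest, 22 were positive with a median of 0.20, 1 passing over all genes and 5 over the list alone (adjusted p = 4.89e-06; 0.620 with an estimated correlation), and Cxcl2 and Ccl7 stood at 1.05 and 1.01. The transcription factors were called upward (median 0.21, 3 over the list alone, adjusted p = 2.7e-04; 0.495 with an estimated correlation), with Atf3 at 1.22 and Junb at 1.13, as did the innate immune list (median 0.15, 0 over the list alone, adjusted p = 5.85e-04; 0.427 with an estimated correlation) and the oviduct markers (median 0.07, 1 over the list alone, adjusted p = 0.0166; 0.694 with an estimated correlation). Ovgp1 differed by 0.33 at 14 h, with 0.72 on a second probe set. Cell cycle genes had negative departures in 29 of 31, with a median of −0.36 and 9 over the list alone (adjusted p = 2.5e-10; 0.411 with an estimated correlation), with Mcm4 at −1.02 and Rrm2 at −0.87. Glycolysis was called downward with a median of −0.33, with 3 genes over the list alone (adjusted p = 0.00109; 0.631 with an estimated correlation), and cholesterol synthesis with a median of −0.32, with 1 gene over the list alone (adjusted p = 0.00178; 0.560 with an estimated correlation). No list passed fry, and the uncalled interferon and apoptosis lists had medians and tests of unlike sign. A departure need not mean a difference at 14 h itself. The transcription factors had a median EP2KO minus WT difference of 0 at 14 h, against −0.14, −0.27 and −0.09 at 0, 3 and 9 h. Glycolysis had −0.08 at 14 h, against 0.31, 0.01 and 0.37 at these times.

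**Figure D3:**
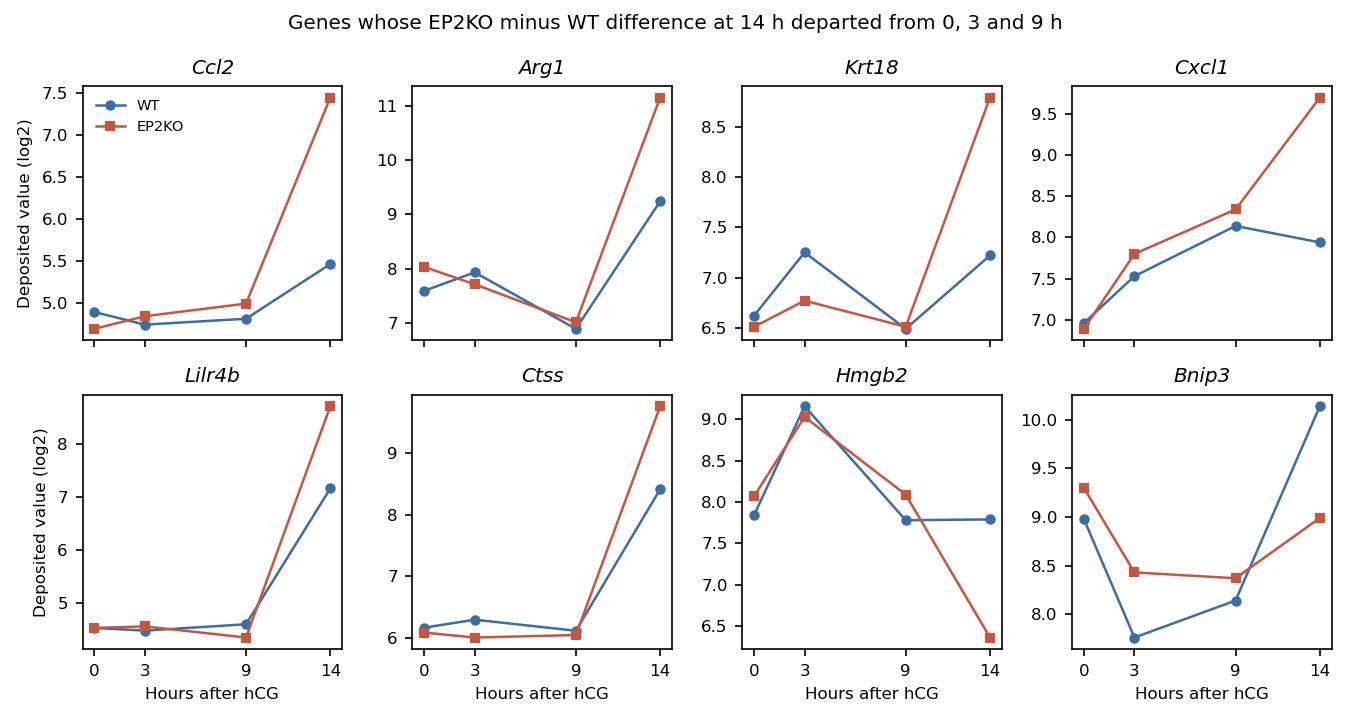
Deposited log2 value (vertical axis) against hours after hCG (horizontal axis) for the 8 genes whose EP2KO minus WT difference at 14 h departed from the earlier times, with 1 array per point, WT in blue circles and EP2KO in red squares. Ccl2 reads 5.46 in WT and 7.44 in EP2KO at 14 h, and Bnip3 reads 10.14 and 8.99.

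At each single time there is 1 array per genotype, so the differences are values with no test. The percentiles ignore correlation between the genes of a list, so extreme ones are common. The 12 genes named as rising most at 3 h all read lower in EP2KO at that time. Of the 58 probe sets that differed at least 2-fold at 3 h, 50 were lower in EP2KO, among them Srxn1 at −1.85, Crem at −1.64, Ell2, a transcription elongation factor, at −1.56, Procr at −1.55, Sowahc at −1.45 and Ptger4 at −1.43. Higher at 3 h were C86187 at 1.53, Cyp1b1, an estrogen-metabolising enzyme, at 1.2, Ackr3 at 1.13, Zp3, a zona pellucida protein of the oocyte, at 1.12, Ccn2 at 1.06 and Bcl2l10 at 1.02. The transcription factor list had a median of −0.27 at 3 h, at percentile 0 of 10000 random lists matched on expression, and the matrix list −0.21, at percentile 0.02. Both lists already read lower in EP2KO at 0 h, with medians of −0.14 at percentile 0.09 and −0.18 at percentile 0.115. At 14 h their medians were 0 at percentile 56.9 and −0.04 at percentile 14.1, in the same order. After quantile normalization the transcription factors had −0.181 at 0 h and −0.169 at 3 h. Oocyte markers stood higher in EP2KO at 3 h in 17 of 20 genes, with a median of 0.36 at percentile 100, and lower at 0 h in 17 of 20, with a median of −0.28 at percentile 0.

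At 0 h 5 probe sets differed at least 2-fold, 3 higher and 2 lower in EP2KO. Prss23, a serine protease, stood at 1.04, Erdr1 at 1.0, Gch1 at 0.90, Aldh1a1 and Hmgcs1 at 0.86 and Frmd5 at 0.79, and Mtm1 at −1.49, Bcl2l10 at −0.77, Bphl at −0.68, Klf6 at −0.64, Plec at −0.60 and Mxd1 at −0.58. Cholesterol synthesis had a median of 0.34 at percentile 100, and chemokines −0.21 at percentile 0.035, with 23 of 25 lower in EP2KO. At 9 h 16 differed, 5 higher and 11 lower. Higher in EP2KO at 9 h were Car14 at 1.38, Tnni3 at 1.03, Mycl at 1.02, Hsd17b1 at 1.0, Inhbb at 0.98 and Dsp, desmoplakin, at 0.90, while the granulosa list had a median of 0.045 at percentile 77.2, with 13 genes higher and 11 lower. All of these single genes but Dsp are among the 12 named for the largest falls by 14 h. Across probe sets the difference at 9 h correlated at −0.548 with the change from 3 to 14 h, which uses other arrays. After quantile normalization it was −0.527. Genes that fell between 3 and 14 h thus tended to read higher in EP2KO at 9 h, as in a sample less far along. That comparison was chosen afterwards, and with 1 array per genotype the stage of the sample was not tested further. Lower at 9 h were the haemoglobin genes Hba-a1 at −2.45 and Hbb-b2 at −2.36, a Wnk1 probe set at −1.32, Ereg at −1.26, Nr4a1 at −1.25 and Xist at −1.09. Glycolysis had a median of 0.37 and the cell cycle 0.25 at 9 h, both at percentile 100. Glycolysis stood at 0.01 at 3 h and −0.08 at 14 h. The 3' minus 5' controls differed most between genotypes at 9 h, by −0.49 for Gapdh and −0.42 for Actb. At 14 h 27 differed, 21 higher and 6 lower. Arg1 stood at 1.91, Cxcl1 at 1.76, Krt18 at 1.57, Lilr4b at 1.55, Erdr1 at 1.36 and Ctss at 1.35, and Bnip3 at −1.15, Hao2 at −1.08, Frmd5 at −1.04, Scd1, a fatty acid desaturase, at −1.02, Suz12 at −0.99 and Ak4 at −0.98. Leukocyte markers were higher in EP2KO in 25 of 28 genes with a median of 0.36 at percentile 100, chemokines in 20 of 25 with a median of 0.15 at percentile 99.6, opposite to 0 h, and the cell cycle list was lower with a median of −0.20 at percentile 0.045.

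**Figure D4:**
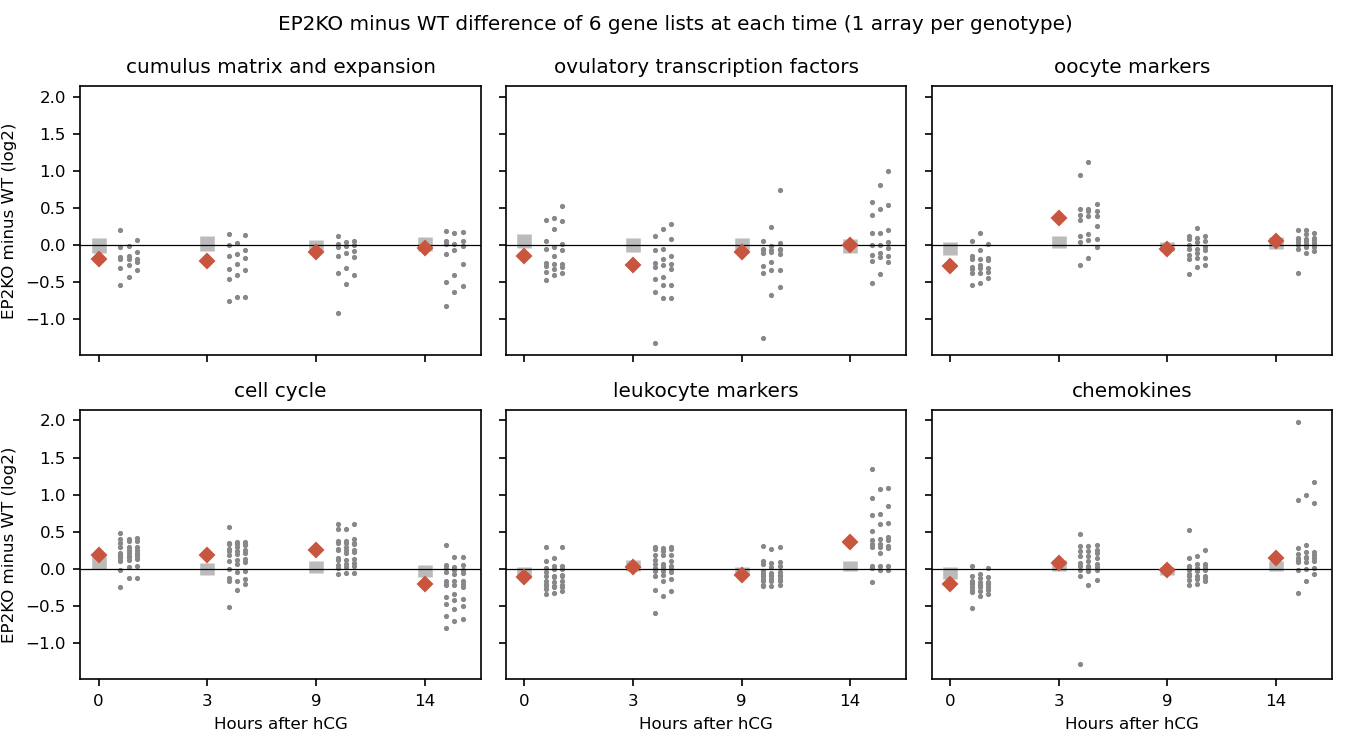
EP2KO minus WT difference on the log2 scale (vertical axis) of 6 gene lists against hours after hCG (horizontal axis), with small grey points for single genes, a red diamond for the list median and a grey bar for the 5th to 95th percentile of random lists matched on expression. The median of the oocyte markers lies at −0.28 at 0 h and 0.36 at 3 h, and that of the leukocyte markers at 0.36 at 14 h.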

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

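The tests of leukocyte, oviduct and RNA quality explanations, of oocyte RNA, array spread and stage at 3 h, and of blood cells at 9 h were chosen only after the results they address had been seen. Percentiles among random lists ignore correlation between genes, so an extreme percentile does not by itself decide between causes.

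The EP2KO minus WT difference at 14 h differed from that at 0, 3 and 9 h by the interaction test for 10 probe sets and 8 gene lists. The 14 h arm of that test is a single pair, assumed to vary like the 3 earlier pairs, so a difference between stages is not shown. After median centring 0 probe sets passed, with Ccl2 at 1.93, and without the 0 h, the 3 h or the 9 h pair 0 passed, with Ccl2 at 1.84, 1.99 and 2.03. A pair left out takes residual degrees of freedom from the test, which alone makes a call hard to reach. The probe sets were those of Ccl2 (1.95), Arg1 (1.80), Krt18 (1.76), Cxcl1 (1.63), Lilr4b (1.61), a probe set without a gene symbol (1.59), Ctss (1.5), a probe set shared by Lilrb4a and Lilr4b (1.48), Bnip3 (−1.56) and Hmgb2 (−1.57), in log2 units. The lists departed in the median by 0.413 for leukocyte markers, 0.21 for ovulatory transcription factors, 0.197 for chemokines, 0.15 for innate immune genes, 0.07 for oviduct epithelium markers, −0.317 for cholesterol synthesis, −0.33 for glycolysis and −0.357 for the cell cycle. With an estimated correlation 0 of these list calls were kept, with adjusted p from 0.411 to 0.694, and 0 lists passed fry. At 14 h itself the transcription factors had a median difference of 0 and glycolysis −0.08, so their departures rest mostly on the earlier pairs.

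Chemokines and myeloid genes stood higher in EP2KO at 14 h, in 1 array per genotype. More oviduct epithelium in the EP2KO sample stays open: Ovgp1, which rose by 3.65 over 0 h, differed by 0.33 on the probe set tested but by 0.72 on a second, the oviduct list was called upward (adjusted p = 0.0166) with its member Krt18 at 1.76, and without Krt18 the list median at 14 h lay at percentile 65.6 with 10 of 18 higher. Poorer RNA in 1 of the samples is argued against, since the Gapdh 3' minus 5' difference between genotypes was −0.05 at 14 h and that of Actb −0.24, against up to −0.49 and −0.42 before. More leukocyte RNA in the EP2KO sample stays open: the 27 leukocyte markers other than the called Ctss had a median of 0.34, at percentile 100 of matched random lists, with 24 of 27 higher. Whether a fixed mix of leukocytes could account for the chemokines cannot be told apart from chemokine expression by cumulus cells, because the median factor of the rise in EP2KO over that in WT, 2.76 for 8 chemokines and 2.72 for 18 leukocyte markers, rests on genes kept for a rise of at least 0.5 log2 in either genotype, some in EP2KO alone, which can raise it, and single factors ran from 0.427 to 9.12 and from 0.93 to 16.5, with Ccl7 and Cxcl1 without a rise in WT. An effect of EP2 loss on these genes in cumulus cells or on leukocyte entry also stays open and was not tested, since each genotype has 1 array at 14 h.

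The 12 genes named as rising most at 3 h were all lower in the EP2KO 3 h array, with a median of −0.96 and a range from −1.85 to −0.07, against −0.25 at 0 h, −0.29 at 9 h and 0.01 at 14 h. Oocyte markers were higher in that array in 17 of 20 genes, with a median of 0.36 at percentile 100. Dilution by oocyte RNA as the cause of the lower induced genes is argued against, since the 24 granulosa genes had a median of 0.01 with members from −0.47 to 0.63, none near the induced genes' median. A different spread of the 2 arrays is argued against as the whole cause, since the median was −0.87 after quantile normalization. A sample that was less far along the response, by time of collection or by a slower response without EP2, stays open: the 957 genes whose probe set with the highest mean was lower at 9 h than at 0 h had, after quantile normalization, a median EP2KO minus WT difference of 0.06 at 3 h, at percentile 100, and the 1009 higher by the same rule had −0.08, at percentile 0. A weaker response for want of EP2, as a biological difference the design names, was not tested apart from this with 1 array per arm. Across probe sets the 3 h difference correlated at −0.297 with the change from 0 to 9 h. The 0 h difference, in samples without hCG, correlated at −0.349 with the change from 3 to 9 h. A correlation of that size therefore does not require a lag after hCG.

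The haemoglobin genes Hba-a1 and Hbb-b2 read 13.39 and 10.34 in WT at 9 h and 10.94 and 7.98 in EP2KO, differences of −2.45 and −2.36. Blood cells in the WT sample cannot be told apart from other causes, because the 4 other erythroid markers, with a median difference of −0.03 and with Alas2 at −0.34, already read from 6.75 to 8.24 in WT at 0 h, high enough to hide a small share of such RNA. No biological explanation was tested.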

How the results depend on the processing

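The tests without both 14 h arrays, without the EP2KO 0 h and 3 h arrays, and the list results after quantile normalization were chosen only after the results had been seen. At 3 h the balance of calls turned from 2161 higher and 3152 lower to 2394 higher and 2111 lower after median centring. Of 1695 values for named genes under alternatives 1625 kept their side of the threshold, 65 lost it and 5 gained it. Most of these genes were picked for the largest time changes or had not passed, so a kept side was likely from the start. The genes named as departing at 14 h lost their call without each earlier pair. Of 268 list calls 178 were kept and 90 lost, and of 64 list medians at single times 62 stayed within the spread and 2 moved, both under quantile normalization (transcription factors at 3 h −0.169, cell cycle at 0 h 0.095). For 3 h against 0 h, 3482 probe sets passed with the lowest 40% left out, 2888 with only the 4 arrays of the 2 times, and 0 without the EP2KO 0 h and 3 h arrays, where fewer arrays were fitted; leaving out 1 array gave from 1897 to 5471, the lowest 2 without WT 0 h (1897) and WT 3 h (1901). The same range was 1225 (without WT 0 h) to 3036 at 9 h, with 1327 without EP2KO 9 h and 1386 without WT 9 h, 2289 (without WT 0 h) to 3809 at 14 h, and 1286 (without EP2KO 9 h) to 2668 for 14 h against 9 h, where only the 4 arrays gave 699. Without both 14 h arrays 5471 passed at 3 h and 2995 at 9 h. The genotype contrast gave 0 to 1 when each pair was left out, the 1 without the 14 h pair. The departure at 14 h gave 0 after median centring, 0 with the lowest 40% left out, 17 with a trend and robust prior, 16 at a threshold of 0.10, and 0 to 0 without each earlier pair. With an estimated correlation 0 lists were called in each of the 6 contrasts. The cumulus matrix list lost its calls although its estimate in the time and genotype contrasts, −0.0359, lay below the preset 0.01. With fry 13 lists passed at 3 h, 1 for the genotype and 0 for the departure; quantile normalization left 4 at 3 h, and leaving out each pair gave 4 (3 h pair) to 12 (14 h pair) for the genotype. At a log2 difference of 1.5 the single times gave 0, 9, 4 and 7 probe sets at 0, 3, 9 and 14 h, and 14 h gave 12 with the lowest 40% left out. The Spearman correlation of the responses was 0.786 at 9 h and 0.698 at 14 h. Fewer probe sets, fewer arrays, a looser threshold and a larger size rule change counts by their construction; for median centring, the trend and robust prior, quantile normalization, fry, the estimated correlation and Spearman's rho the cause was not tested. Signal over background limits genes of low expression such as Ptger2 and Ccl2, whose probe sets lie at percentiles 7.58 and 9.87 of mean expression.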

Other observations

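The test of genes next to Ptger2 was set before its result was seen; the splits and the correlations along the time course were chosen only afterwards.

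Several single genes, picked after their values were seen, differed in direction between times or from other members of their list. Cks2, a partner of the mitotic kinase, rose by 1.27 at 3 h and 1.08 at 9 h before standing at 0.33 at 14 h, where 28 other cell cycle genes had fallen. Pparg rose by 1.25 at 3 h and fell by 2.12 at 14 h, and Ptges rose by 1.19 at 3 h and fell by 1.43 at 14 h, while Ptgis, prostacyclin synthase, stood at −1.33 at 9 h and −2.20 at 14 h. Mmp14, a membrane protease, fell by 1.01 at 3 h and rose by 0.95 at 14 h. Inhba rose by 0.51 at 3 h and fell by 2.14 at 14 h, and Kitl, the ligand of Kit on the oocyte, rose by 0.54 at 3 h and fell by 0.84 at 9 h. In glycolysis Hk1 rose by 1.44 at 3 h and fell by 0.65 at 14 h, while Pgk1 rose by 0.94 at 3 h and 0.71 at 14 h and Ldhb fell by 1.65 at 14 h.

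Single genes of protein folding differed in direction at 14 h. Pdia4 fell by 0.90 at 3 h and rose by 0.81 at 14 h, Pdia3 rose by 1.26 and 1.62 and Atf6, a sensor of the unfolded protein response, by 0.36 and 1.42 at these times, while Herpud1 and Dnajc3 fell, to −1.30 and −1.27, at 14 h. Among the apoptosis regulators Cdkn1a, a cell cycle inhibitor, rose by 1.36 at 3 h and 0.94 at 14 h, Mcl1 rose by 0.82 at 14 h and Bad fell by 0.91 at 3 h.

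The genotype labels can be swapped within times in 8 ways, which are too few for a share under 0.05. The real split gave 0 probe sets past the threshold and the highest other split 0, so 8 of 8 were at least as large. At an unadjusted p under 0.05 the real split had 642 and the highest other 1406. That other split swaps the labels at 3 and 14 h, which sets the 0 and 9 h pairs against the 3 and 14 h pairs. The 3' minus 5' Gapdh control differed between genotypes by −0.38 and −0.49 at 0 and 9 h. At 3 and 14 h it differed by 0.16 and −0.05. Whether RNA quality or another structure of the samples lies behind that split was not tested.

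A candidate explanation for part of the unadjusted genotype differences is DNA from the embryonic stem cell strain carried along next to the targeted gene. Among the 25 measured genes on each side of Ptger2, 8 of 61 probe sets had p under 0.05 (13.1%), against 576 of 10771 elsewhere (5.35%), with p = 0.0161 in a one-sided Fisher's exact test. They were Ghitm with 2 probe sets (−0.41 and −0.24), counted apart in the test, Bmpr1a (−0.36), Apex1 (0.27), Ddhd1 (0.22), Oxnad1 (−0.21), Ncoa4 (−0.27) and Glud1 (−0.24). Carried-along DNA is present at every time. Yet at 0, 3, 9 and 14 h Bmpr1a differed by −0.06, −0.36, −0.39 and −0.62. Ncoa4 differed by 0.10, −0.16, −0.37 and −0.64, and Glud1 by 0.02, −0.18, −0.19 and −0.62. Ddhd1 (0.18, 0.39, 0.18 and 0.12) and the first Ghitm probe set (−0.26, −0.34, −0.27 and −0.79) already differed at 0 h. Over all probe sets 642 had p under 0.05 where 621 are due, so there was little excess to explain. The strain of the stem cells is not given in the sources used here, and none of these probe sets passed after adjustment. Neighbouring genes may also share regulation, so carried-along DNA remains a hypothesis.

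Across probe sets, which are not independent replicates, the EP2KO minus WT difference at 3 h correlated at −0.297 with the change from 0 to 9 h, the difference at 9 h at −0.548 with the change from 3 to 14 h, the difference at 0 h at −0.349 with the change from 3 to 9 h, and the difference at 14 h at −0.0512 with the change from 0 to 9 h. Erdr1 stood higher in EP2KO by 1.0, 0.14, 0.46 and 1.36 at 0, 3, 9 and 14 h on its named probe set. Mtm1 differed by −1.49, 0.10, −0.33 and 0.99 on its named probe set at the same times.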
